A study of Danio rerio with 24 samples.

How the data were processed

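Poly-A RNA from whole zebrafish embryos was sequenced in 24 samples that form 2 sets. The germline set holds 12 single embryos of 5 dpf from an incross of alx1 mutants carrying alx3, per the labels, with 4 embryos each of the genotypes alx1, alx1;alx3/+ and alx1;alx3. The 72 hpf set holds 6 WT samples and 6 samples of CRISPANTs, embryos mutated by guide RNAs at the injected generation, here with several alx3 guides injected into alx1 embryos. The labels do not say whether a 72 hpf sample was a single embryo or a pool, so p-values in that set measure only the spread between these samples. All embryos were kept at 29 °C. Per the labels, libraries were prepared with a TruSeq stranded kit in the germline set and with a NEBNext directional kit in the 72 hpf set.

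Per the submitters' processing notes, the genome build was danRer10, and the notes name STAR 2.5.3a and 2.7.1a, Trimmomatic 0.36, RSEM 1.3.0, featureCounts and Subread 2.0 without saying which tool served which set. Per the file headers, the germline values deposited by the authors are expected counts of RSEM, which estimates counts for reads shared between transcripts, together with TPM and the effective length of each gene. In 1 germline embryo the deposited table was at transcript level (59876 transcripts), and its expected counts were summed per gene. TPM by the authors, per the file headers, served only to weight transcript lengths within a gene. The 72 hpf values are whole-number counts per gene in a table with the column layout of featureCounts, per the file headers, beside each gene's summed exon length. The annotation release, the strand setting and the treatment of multi-mapped reads are not given in the sources used here, so reads of near-identical copies, such as duplicated trypsin, crystallin and actin genes, may be divided between the copies or left out.

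The germline files hold 32520 genes and there are 34326 in the 72 hpf table, of which 28211 identifiers occur in both. Gene symbols came from a table of Ensembl identifiers and, for human-style symbols, from a RefSeq gene table. They named 29201 germline genes and 26803 genes of the 72 hpf table. Coordinates are those of the 72 hpf table and were passed to germline genes with the same identifier. No reference genome was used.

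Expected counts were rounded to whole numbers before testing. Total counts ran from 9.7 to 33 M (M, mega) per germline embryo and from 26.8 to 49.8 M per 72 hpf sample. Genes were kept by edgeR's filterByExpr (edgeR 4.0.16, R 4.3.3, limma 3.58.1), which left 20790 and 21594 genes. Each set was fitted on its own with TMM factors and edgeR's robust quasi-likelihood F test, with group as the only term. The germline fit used all 12 embryos, which shared 1 estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The groups compared were alx1;alx3 against alx1, alx1;alx3/+ against alx1, alx1;alx3 against alx1;alx3/+, and CRISPANT against WT. Log2 fold changes have their standard errors (SE), and levels are CPM, counts scaled by library size and TMM factor, with the SD between samples. Counting error is only part of that spread.

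On simulated counts with 200 changed genes, the same steps recovered 7.46% of 1.5-fold, 49.3% of 2-fold and 90.9% of 4-fold changes in alx1;alx3 against alx1, with 3 false calls. In alx1;alx3/+ against alx1 the shares were 5.97%, 38.8% and 86.4% with 2 false calls, and in alx1;alx3 against alx1;alx3/+ they were 4.48%, 35.8% and 81.8% with 2 false calls. In CRISPANT against WT they were 73.1%, 95.5% and 100% with 11 false calls. The changed genes were drawn from genes above a minimum mean count, with independent noise for each gene. Where fewer genes are called, as in the real germline fits, the Benjamini-Hochberg threshold is stricter. The shares may therefore overstate recovery in the germline set. The biological coefficient of variation was 0.253 in the germline set and 0.099 in the 72 hpf set.

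The designs, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The 30 lists cover Alx paralogs, paired homeobox relatives, cranial neural crest, cartilage, bone, the optic fissure, the periocular mesenchyme and anterior segment, lens, photoreceptors, the inner retina, the retinal pigment epithelium with the retinoid cycle, retinoic acid signalling, melanophores, iridophores with xanthophores, central neurons, myelin and glia, muscle, heart, vasculature, erythroid cells, innate immunity, interferon, skin, liver, intestine, exocrine pancreas, the circadian clock, the cell cycle, the p53 response, and heat, endoplasmic reticulum and immediate-early stress. Of 1241 list symbols, 1143 matched a gene. A list was tested where at least 5 members were kept, which left the Alx paralogs untested as a list. Lists were tested two-sided with camera at a preset correlation of 0.01, and again with the estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes are the Alx genes, the 10 genes of smallest p in each direction among those past the threshold that have a gene symbol other than a clone or locus name, the 5 of smallest p in a direction where none passed, and up to 4 members of smallest p past the threshold from each list. Other genes named were chosen after their values were seen, and this is said beside them.

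Whether called genes gathered on the chromosomes of alx3 and alx1 was tested with two-sided Fisher's exact tests against the other chromosomes. These tests take genes as independent, which linked genes in the same embryos are not. Their p-values and intervals do not measure the spread between embryos or samples. Genes called in CRISPANTs were tested as lists in the germline fit with camera. The alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no filter or a stricter filter of 1 CPM, leaving out each embryo or sample in turn, the replicate number as a block, leaving out the 100 most abundant genes, leaving out the chromosomes of the mutated genes, only the 2 genotypes compared, effective-length offsets, and the letter that starts each germline file's name as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.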

Results

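The alx1, alx3, alx4a and alx4b genes encode the Alx homeodomain transcription factors, which act in the cranial neural crest that builds the face and the front of the eye. To ask what losing alx3 adds to the loss of alx1, whole-embryo RNA was compared between 4 alx1, 4 alx1;alx3/+ and 4 alx1;alx3 embryos at 5 dpf. A further 6 CRISPANT samples, alx1 embryos injected with alx3 guides, were compared with 6 WT samples at 72 hpf. Total counts were 10.3 to 23.1 M (M, mega) in alx1, 9.7 to 13.7 M in alx1;alx3/+ and 11.5 to 33 M in alx1;alx3 embryos, and 28.7 to 49.8 M in WT and 26.8 to 33.3 M in CRISPANT samples. The sets differ in age, library kit and control genotype, so levels were compared only within a set.

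In the germline embryos, alx3 (ENSDARG00000111246) was found at 1.29 ± 0.414 CPM in alx1, 1.16 ± 0.723 CPM in alx1;alx3/+ and 0.615 ± 0.513 CPM in alx1;alx3 embryos (SD, n = 4 each). The log2 fold change between alx1;alx3 and alx1 was -1.18 (SE 0.60), which did not pass (edgeR quasi-likelihood adjusted p = 0.374). It was -0.16 (adjusted p = 0.988) for alx1;alx3/+ against alx1 and -1.02 (adjusted p = 0.999) for alx1;alx3 against alx1;alx3/+ with the same test. With 6 to 31 counts per embryo, alx3 level did not separate the genotypes: alx1;alx3 replicate 2 had 1.33 CPM, above 3 of the 4 alx1 embryos. alx1 itself (ENSDARG00000062824) was transcribed at 2.41 ± 1.08, 2.38 ± 0.88 and 2.59 ± 1.3 CPM in the 3 genotypes (SD, n = 4 each), alx4a at 25.4 ± 4.91, 25.1 ± 5.9 and 25.8 ± 2.94 CPM, and alx4b at 4.05 ± 1.33, 3.76 ± 1.06 and 3.41 ± 0.972 CPM. None of alx1, alx4a and alx4b passed in any germline comparison, with edgeR adjusted p from 0.737 to 0.999.

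In the 72 hpf set, alx1 on chromosome 18 (16257740 to 16265680, danRer10) fell from 5.61 ± 0.498 CPM in WT to 2.79 ± 0.484 CPM in CRISPANTs (SD, n = 6 each), a log2 fold change of -1.0 (SE 0.11, edgeR quasi-likelihood adjusted p = 5.17e-05), with no overlap between the groups. alx4a rose by 0.26 on the log2 scale, from 31.3 ± 1.32 to 37.4 ± 3.4 CPM (edgeR adjusted p = 0.0077), and alx4b had a log2 fold change of -0.27, from 7.54 ± 0.589 to 6.28 ± 0.545 CPM (edgeR adjusted p = 0.0256). The alx4b call was lost without WT replicate 1, 3 or 5 or CRISPANT replicate 1, 2 or 4, with edgeR adjusted p of 0.0506 to 0.0603. No row of the 72 hpf table is named alx3, so its level there was not analysed here. An unnamed gene, ENSDARG00000091086 (chromosome 8, 24777393 to 24788908), lies between rbm15 and slc6a17, the neighbours of alx3 in the RefSeq gene order. It was chosen after its values were seen and fell from 9.6 ± 1.02 to 4.23 ± 0.749 CPM (SD, n = 6 each), a log2 fold change of -1.18 (SE 0.11, edgeR adjusted p = 1.36e-05).

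**Figure D1:**
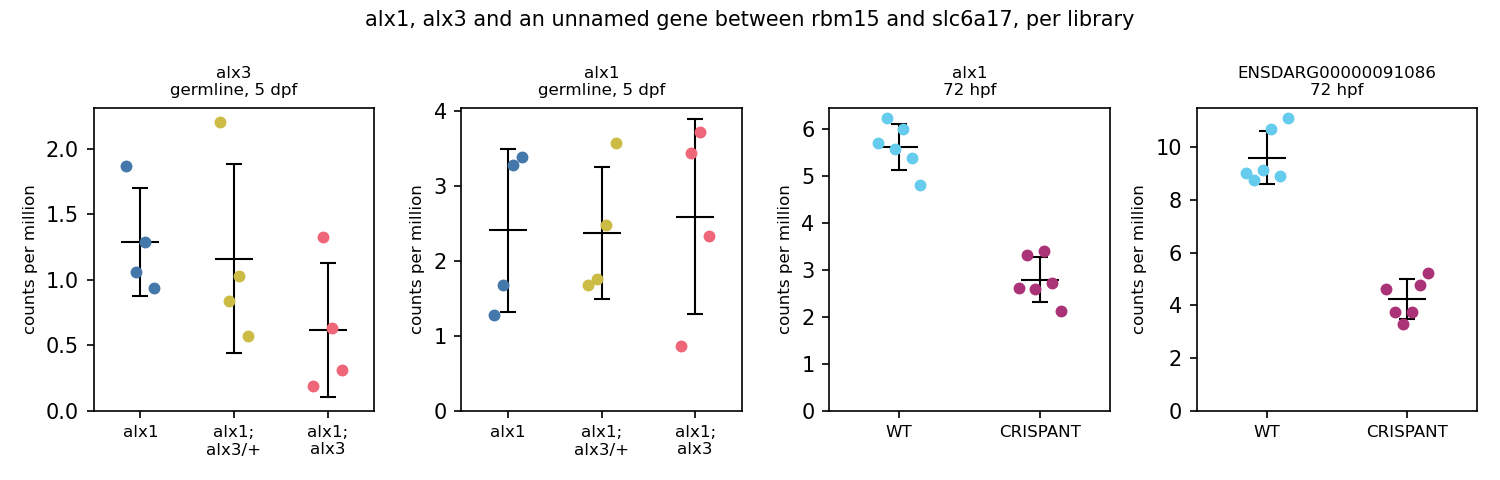
CPM of alx3 and alx1 in the germline embryos (n = 4 per genotype), and of alx1 and the unnamed ENSDARG00000091086 in the 72 hpf samples (n = 6 per group), where each point is a library and bars give the mean and SD. The genotypes overlap for alx3, while alx1 lies at 5.61 CPM in WT and 2.79 CPM in CRISPANTs.

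The first germline comparison, alx1;alx3 against alx1, asks what differs between alx1 embryos with and without homozygous alx3 mutation. The comparison does not separate alx3 from alleles linked to it. Lower in alx1;alx3 embryos were p2rx7, which encodes an ATP-gated ion channel, elovl8b, which encodes a fatty acid elongase, and the clone-named genes si:ch73-237c6.1 and si:ch73-281k2.5, included after their values were seen because they complete the 4 genes that passed. p2rx7 (ENSDARG00000042440, 30748937 to 30769869) went from 3.98 ± 0.786 CPM in alx1 to 0.0609 ± 0.0754 CPM in alx1;alx3 embryos (SD, n = 4 each), where no embryo had more than 4 counts. elovl8b (ENSDARG00000057365, 18164621 to 18167630) went from 3.68 ± 1.38 to 0.539 ± 0.168 CPM. si:ch73-237c6.1 (ENSDARG00000078114, 23654778 to 23681186) went from a mean of 34 to 4.06 CPM, and si:ch73-281k2.5 (ENSDARG00000104329, 19482209 to 19488256) from a mean of 6.96 to 1.6 CPM. All 4 genes lie on chromosome 8, the chromosome of alx3, between 1.1 and 6.6 Mb from the interval between rbm15 and slc6a17.

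The log2 fold changes were -5.84 (SE 0.72, adjusted p = 0.0124) for p2rx7 and -2.71 (SE 0.38, adjusted p = 0.0311) for elovl8b in edgeR's quasi-likelihood test. They were -3.06 (SE 0.29, adjusted p = 0.000975) for si:ch73-237c6.1 and -2.12 (SE 0.30, adjusted p = 0.0311) for si:ch73-281k2.5 in the same test. Each gene was lower in 4 of 4 embryos, which adds no evidence of its own because the genes were picked by their p. The 4 genes out of 857 tested on chromosome 8 stand against 0 of 19001 on the other chromosomes (Fisher's exact p = 3.45e-06). Linked genes in the same embryos are not independent, so this p does not measure the spread between embryos. At an adjusted p under 0.1 the odds ratio was 89.3 (Fisher's exact p = 4.86e-10), but at an unadjusted p under 0.01 it was 1.63 (0.0023). No gene passed in the raised direction, and the raised genes of smallest p that have a symbol were gpr158b (log2 0.84, SE 0.14, edgeR adjusted p = 0.066), dennd4a, zbtb22a, igfbp7 and cfp, with edgeR adjusted p from 0.156 to 0.165 for the last 4. DESeq2 called 165 genes, 77 raised and 88 lowered, of which 25 lie on chromosome 8, 136 on other chromosomes and 4 have no position, and gave all 5 of these raised genes an adjusted p of 0.00219 or less.

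The number of calls in alx1;alx3 against alx1 changed with single embryos, while the fold changes of the 4 genes stayed large. Without alx1 replicate 1 it became 1105 genes, 862 raised and 243 lowered, of which 58 lie on chromosome 8, and leaving out any other embryo gave 1 or 2. si:ch73-237c6.1 kept its call in all 8 such fits (edgeR adjusted p 0.00137 to 0.014). Its interval overlaps that of cfp (ENSDARG00000094451, 23651015 to 23681056), whose mean went the other way, from 26.6 to 51.3 CPM, and a shift of reads between these overlapping gene models was not tested. p2rx7 lost it without alx1 replicate 3 or 4 or alx1;alx3 replicate 2 or 3 (edgeR adjusted p 0.0561 to 0.0869), with log2 fold changes of -7.19 to -5.26 over the 8 fits. elovl8b and si:ch73-281k2.5 each kept it only without alx1 replicate 1 (edgeR adjusted p 0.0257 for both) and reached 0.183 and 0.184 in the other fits, with log2 fold changes of -2.96 to -2.4 and -2.29 to -1.96. elovl8b also lost its call with the file letter as a block (edgeR adjusted p = 0.071), with only the 2 genotypes compared (0.0862) and with effective-length offsets (0.0942). The replicate number as a block ended the calls of both p2rx7 and elovl8b (edgeR adjusted p = 0.168 for each).

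No fixed list had a member past the threshold over all genes in alx1;alx3 against alx1 (edgeR quasi-likelihood), where 3032 of 20790 genes had an unadjusted p under 0.05. Lower in alx1;alx3 embryos were 54 of 58 liver genes (median log2 -0.47), 38 of 43 intestine genes (-0.62), 31 of 32 exocrine pancreas genes (-1.01) and 62 of 71 cell cycle genes (-0.22). Higher were 38 of 42 cartilage genes (median log2 0.51), 46 of 53 central neuron genes (0.26), 30 of 35 optic fissure genes (0.32), 36 of 46 cranial neural crest genes (0.22), 26 of 33 inner retina genes (0.27) and 19 of 25 melanophore genes (0.39). Adjusted over the list alone, 8 liver, 8 intestine, 2 erythroid, 1 exocrine pancreas and 1 myelin and glia genes were lower. Adjusted over the list alone, 5 retinal pigment epithelium genes were higher and 2 lower, 1 retinoic acid gene was higher and 2 lower, and 1 melanophore, 1 circadian and 1 paired homeobox gene were higher.

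Camera with its preset correlation passed 19 of 29 lists in alx1;alx3 against alx1, 12 of them up. Its adjusted p was 2.7e-12 for liver, 1.62e-09 for intestine, 5.59e-11 for exocrine pancreas, 5.97e-08 for both cartilage and central neurons, and 1.53e-07 for the optic fissure. With the estimated correlation no list passed (smallest camera adjusted p = 0.28), nor did any with fry (smallest adjusted p = 0.0881), so none of these lists is reported as changed. The cell cycle, inner retina, cranial neural crest, melanophore, paired homeobox, vasculature, circadian, periocular, retinal pigment epithelium, photoreceptor, skin, erythroid and innate immunity lists also passed with the preset correlation alone (camera adjusted p 9.51e-07 to 0.0372). The bone, muscle, heart, interferon, iridophore, lens, myelin and glia, p53, retinoic acid and stress lists did not pass (camera adjusted p 0.0748 to 0.889). The lens and p53 lists had medians of -0.02 and -0.07 but means of 0.09 and 0.01 and an upward test. The preset test lost the erythroid, innate immunity and skin lists without alx1 replicate 4 (camera adjusted p = 0.0574 for each) and the periocular list without alx1 replicate 3 (0.0638). It lost the circadian list without alx1 replicate 1 (0.0698) or 4 (0.14), and the retinal pigment epithelium list without alx1 replicate 1 (0.0698) or 4 (0.162) or alx1;alx3 replicate 1 (0.0728) or 3 (0.0648). Photoreceptors were lost without alx1;alx3 replicate 1 (0.0728) or 3 (0.0848) and turned downward without alx1 replicate 4 (0.317). It gained bone without alx1 replicate 1 (0.0465), lens without alx1 replicate 2 (0.0291), muscle without alx1 replicate 2 (0.0139) or 3 (0.000871), and stress without alx1 replicate 2 (0.00946) or alx1;alx3 replicate 4 (0.0462). Interferon was gained without alx1 replicate 1 (0.0407) or 2 (0.0185) or alx1;alx3 replicate 2 (0.0358) or 4 (0.0462). Without alx1 replicate 1 both bone and interferon had a camera adjusted p of 0.347 with the estimated correlation, and the other gained calls were not tested with it.

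The comparison of alx1;alx3/+ with alx1 asks whether a single mutant copy of alx3 has an effect. Lower were p2rx7, elovl8b and si:ch73-237c6.1, 3 of the 4 genes called in alx1;alx3 embryos. p2rx7 was at 0.0727 ± 0.0901 CPM and elovl8b at 0.398 ± 0.151 CPM in alx1;alx3/+ embryos (SD, n = 4), against 3.98 and 3.68 CPM in alx1, and si:ch73-237c6.1 had a mean of 4.51 CPM against 34 CPM. Their log2 fold changes were -5.69 (SE 0.77, edgeR adjusted p = 0.0239), -3.21 (SE 0.42, edgeR adjusted p = 0.0215) and -2.94 (SE 0.29, edgeR adjusted p = 0.00201). si:ch73-281k2.5 did not pass (log2 -1.71, edgeR adjusted p = 0.227). The 3 genes of 857 on chromosome 8 stand against 0 of 19001 elsewhere (Fisher's exact p = 8.01e-05, which again takes linked genes as independent). Leaving out any of the 8 embryos ended the p2rx7 call (edgeR adjusted p 0.0507 to 0.191), though its log2 fold change stayed at -6.71 to -5.21. elovl8b kept its call in 3 of 8 such fits (edgeR adjusted p 0.0425 to 0.181, log2 -3.49 to -2.9), and si:ch73-237c6.1 in 8 of 8 (0.000577 to 0.0216). elovl8b also lost its call with limma-voom (adjusted p = 0.148), effective-length offsets (edgeR adjusted p = 0.238) and the file letter as a block (0.0533), and p2rx7 with the file letter (0.0653). The replicate number as a block ended both calls as well (edgeR adjusted p = 0.155 for elovl8b). The gene count became 1 without alx1 replicate 2 or alx1;alx3/+ replicate 1, 2 or 4. DESeq2 called 19 genes, 13 on chromosome 8, 5 elsewhere and 1 without a position, limma-voom called 4, and 907 genes had an unadjusted edgeR p under 0.05. The raised genes of smallest p that have a symbol, igfbp7, rdh20, dock8, dennd4a and cfp, had edgeR adjusted p from 0.476 to 0.626.

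Over all genes no list member passed in alx1;alx3/+ against alx1 (edgeR), and adjusted over the list alone 1 exocrine pancreas and 1 iridophore and xanthophore gene were lower. Lower were 30 of 32 exocrine pancreas genes (median log2 -0.63, camera adjusted p = 1.05e-12), and higher were 37 of 42 cartilage genes (0.34, 1.44e-06) and 32 of 35 optic fissure genes (0.25, 2.38e-06). Camera with the preset correlation passed 18 of 29 lists, 10 of them up, but none with the estimated correlation (smallest camera adjusted p = 0.208) or with fry (smallest adjusted p = 0.228).

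The comparison of alx1;alx3 with alx1;alx3/+ asks what differs between embryos with 2 mutant copies of alx3 and those with 1. No gene of 20790 passed in edgeR's quasi-likelihood test, 809 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 9. Without alx1;alx3 replicate 1 edgeR called 1 gene. The genes of smallest p that have a symbol were ITGB1, with a log2 fold change of -0.97, hmox1a, itpkcb, hvcn1 and ucp2 on the lower side and erv, sh3bp5a, insig1, pcdh1g9 and HTRA2 on the higher side (edgeR adjusted p = 0.999 for all 10). hmox1a encodes heme oxygenase and had a mean of 12.8 ± 4.6 CPM in alx1;alx3 against 40.6 ± 15.6 CPM in alx1;alx3/+ embryos (SD, n = 4 each), which did not pass in edgeR. DESeq2 passed hmox1a (adjusted p = 0.00479), ITGB1 (0.00637), itpkcb and hvcn1 (0.0392 for both). Camera with the preset correlation passed 10 of 29 lists, 7 of them up, including liver (median log2 -0.34, camera adjusted p = 7.38e-11) and central neurons (0.14, 1.34e-05). None passed with the estimated correlation (smallest camera adjusted p = 0.713) or with fry (smallest adjusted p = 0.742).

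**Figure D2:**
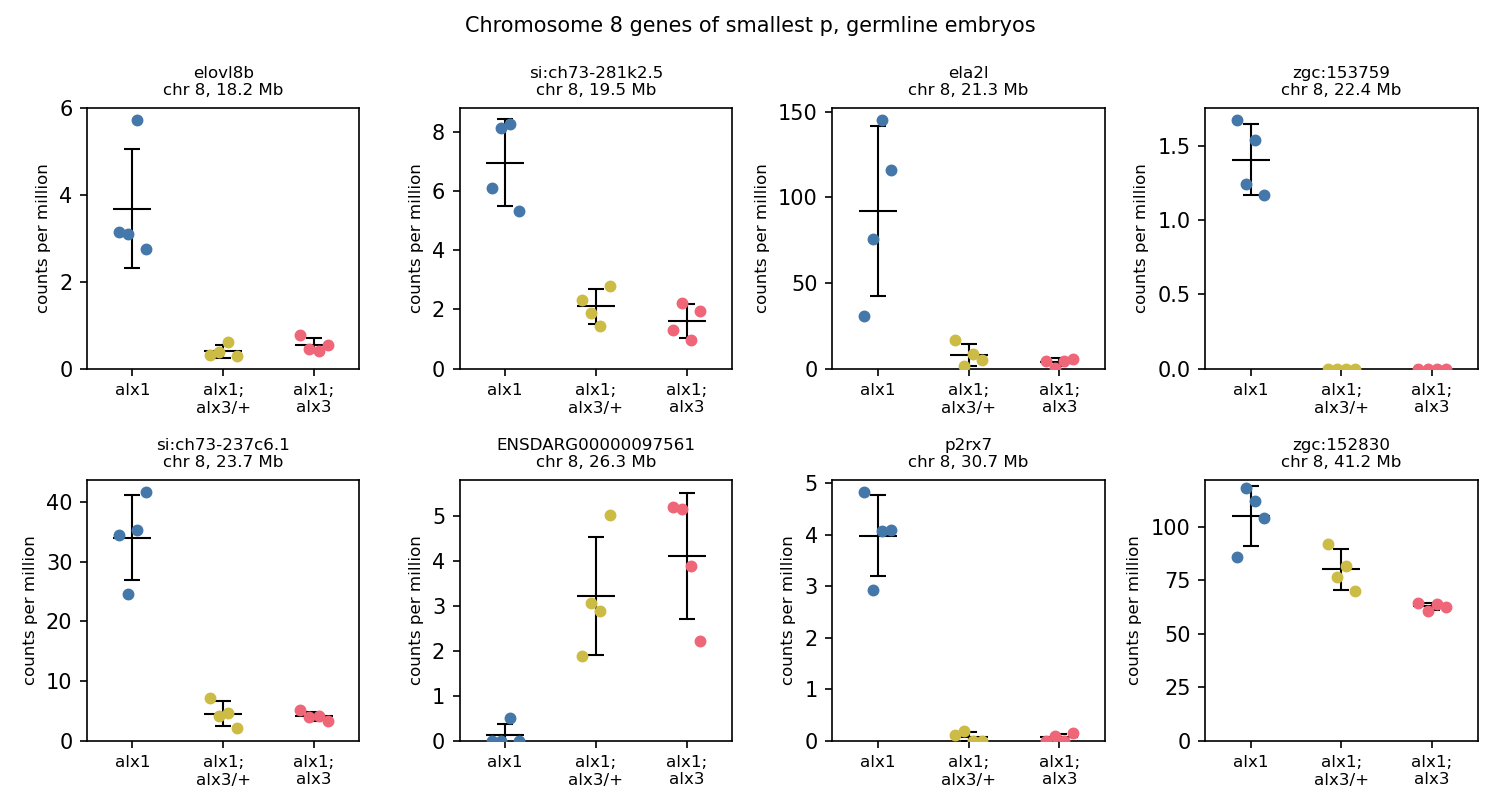
CPM in each germline embryo (points, n = 4 per genotype, with mean and SD) of the 8 genes on chromosome 8 with an adjusted p under 0.1 in alx1;alx3 against alx1. The alx1;alx3/+ embryos lie near the alx1;alx3 embryos for most of them, such as si:ch73-237c6.1 with means of 34, 4.51 and 4.06 CPM in alx1, alx1;alx3/+ and alx1;alx3.

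CRISPANT against WT at 72 hpf asks what the loss of alx1 with injected alx3 guides changes before the larva matures. Of 21594 genes, 2213 rose and 1811 fell (edgeR quasi-likelihood adjusted p under 0.05), with a median absolute log2 fold change of 0.29 among them. Only 142 rose and 68 fell by 2-fold or more. The list counts below are to be read against the 2213 raised and 1811 lowered of 21594 genes. A list near those shares is not set apart by its count. In 1653 of the called genes the groups did not overlap, which adds no evidence of its own because these genes were picked by their p. The chance share of 0.216% holds for genes not picked in this way. The test found 4050 genes with limma-voom and 4518 with DESeq2, and 2839 to 4639 with single samples left out. Because nothing says that the 6 samples per group came from separate clutches, these p-values measure only the spread between these samples, and parents, genotype and injection differ together between CRISPANT and WT.

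Among the 10 raised genes of smallest p, C7H19orf12 rose from 16.5 ± 0.994 to 27.3 ± 1.21 CPM (SD, n = 6 each; log2 0.73, SE 0.05, edgeR adjusted p = 1.28e-06). cyba, which encodes a subunit of the phagocyte NADPH oxidase, rose from 6.63 ± 0.84 to 16.2 ± 2.87 CPM (log2 1.28, SE 0.12, edgeR adjusted p = 1.36e-05), and uraha, a gene of urate breakdown, from 12 ± 1.32 to 27.1 ± 4.69 CPM. The chemokine gene ccl25b (log2 0.73), the kinase gene mapk6 (0.57), fndc7b (1.42), the actin gene actc1c (0.82), the glial calcium-binding protein gene s100b (0.88), fndc7rs4 (0.82) and acte1 (0.58) completed them (edgeR adjusted p 1.36e-05 to 4.42e-05). DUOXA1, which encodes a maturation factor of dual oxidase, fell from 1.3 ± 0.209 to 0.245 ± 0.0977 CPM (log2 -2.40, SE 0.22, edgeR adjusted p = 1.36e-05). Besides alx1, serf2a (-1.02), ccdc171 (-1.06), lypc (-0.87), psip1b (-0.71), hnrnpa3, akap12a (-1.11), tchp and cd82b (-0.51) also fell (edgeR adjusted p 1.98e-05 to 7.73e-05). All of these genes separated the groups in 6 of 6 samples, which adds no evidence of its own because they were picked by their p.

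Pigment cell genes differed in both directions. Of 24 melanophore genes 16 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell. The melanin synthesis genes oca2 (log2 0.35, edgeR adjusted p = 0.000696), tyrp1a (0.32) and tyrp1b (0.36) rose. All 6 CRISPANTs lay above all 6 WT samples for each, though these genes too were picked by their p. The iridophore and xanthophore list had 5 raised and 5 lowered of 33 genes (6 and 6 adjusted over the list alone), with apoda.1 (-0.50) and the purine synthesis gene pnp4a (-0.36) lower. Without WT replicate 6 the melanophore counts were 15 raised and 1 lowered. Camera gave an adjusted p of 4.33e-06 for melanophores, 0.347 with the estimated correlation, and 0.394 for the iridophore and xanthophore list.

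Of 44 clock genes 20 rose and 2 fell in CRISPANTs, and 24 and 2 adjusted over the list alone. The light-induced cryptochrome gene cry1a rose from 8.97 ± 0.917 to 41.7 ± 20.6 CPM (SD, n = 6 each; log2 2.22, edgeR adjusted p = 0.00326), and hlfa (0.42), nr1d2b (0.66) and nfil3-6 (0.57) rose. Of 55 stress genes 19 rose and 2 fell, and 22 and 4 adjusted over the list alone, including the immediate-early genes egr1 (log2 0.95, edgeR adjusted p = 0.00216), nr4a1 and nr4a3 (0.69) and the small heat shock protein gene hspb1 (0.40). Camera adjusted p was 1.63e-05 for the clock and 0.000228 for stress, 0.312 and 0.347 with the estimated correlation.

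Of 27 retinoic acid genes 7 rose and none fell over all genes, and 10 rose and 2 fell adjusted over the list alone, with the retinol receptor gene stra6 (log2 0.30, edgeR adjusted p = 0.00479), the retinoic acid hydroxylase genes cyp26b1 (0.29) and cyp26c1 (0.68), and dhrs3a (0.74) raised. Of 19 retinal pigment epithelium genes 4 rose (7 rose and 2 fell adjusted over the list alone), including rlbp1b (0.39). Of 27 myelin and glia genes 6 rose and 1 fell (7 and 2 adjusted over the list alone), with fabp7b (0.49) raised and olig1 (-0.35) lowered. Camera adjusted p was 0.0072, 0.0172 and 0.0165 in that order, and 0.312, 0.569 and 0.312 with the estimated correlation.

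Of 15 exocrine pancreas genes 7 rose (7 adjusted over the list alone), with the carboxypeptidase gene CPA1 at log2 0.44 (edgeR adjusted p = 0.0099). Of 54 liver genes 10 rose (10 adjusted over the list alone), with the complement gene cfb (0.62) and cyp3a65 (1.32) among them, and of 31 intestine genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with the chitinase gene chia.6 (0.71) up and FABP1 (-0.34) down. The scavenger receptor gene marco (log2 1.26, edgeR adjusted p = 6.24e-05) and the antimicrobial peptide gene leap2 (1.91) rose with 8 of 52 innate immunity genes, where 2 fell (8 and 2 adjusted over the list alone). Of 20 interferon genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with ifi27.1 (1.62) and b2m (1.11) raised and eif2ak2 (-0.45) lowered. Of 36 p53 response genes 8 rose and 2 fell (10 and 2 adjusted over the list alone), with plk2b and the cyclin gene ccng1 raised. The list also holds 2 genes with the symbol RRM2, 1 raised and 1 lowered, which are in the cell cycle list too. Camera adjusted p was 0.000228 for pancreas, 0.00248 for liver, 0.00946 for intestine, 0.0606 for innate immunity, 0.0176 for interferon and 0.0172 for p53, and 0.536 to 0.754 with the estimated correlation. Without WT replicate 6 the counts became 6 raised and 4 lowered for innate immunity, 5 and 2 for interferon and 6 and 2 for intestine. Without the same sample interferon did not pass (camera adjusted p = 0.0561), and innate immunity passed without WT replicate 2 (0.00926) or 3 (0.0436) or CRISPANT replicate 3 (0.0202), 5 (0.0494) or 6 (0.00822).

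Of 71 cell cycle genes 1 rose and 15 fell (1 and 20 adjusted over the list alone), with the kinase gene aurkb (log2 -0.28, edgeR adjusted p = 0.00363) and the replication helicase gene mcm7 (-0.31) down. The 2 members of smallest p share the symbol RRM2 and went opposite ways. ENSDARG00000020711 rose (log2 0.65, edgeR adjusted p = 0.00148) and ENSDARG00000078069 fell (-0.36, edgeR adjusted p = 0.00162). Of 51 central neuron genes 3 rose and 11 fell (4 and 14 adjusted over the list alone), with the neurofilament genes nefmb (-0.33) and nefma (-0.25) and the synaptic gene cplx2a (-0.23) down and th, which encodes tyrosine hydroxylase, up (0.38). Of 32 inner retina genes 3 fell (2 adjusted over the list alone), with lhx1a (-0.26) and the retinal progenitor and bipolar cell gene vsx2 (-0.37) among them. In the lens list 44 of 55 genes were lower (median log2 -0.27), of which 1 passed over all genes and 0 adjusted over the list alone (edgeR). Camera adjusted p was 9.72e-05, 0.00044, 0.0458 and 0.00907 in that order, and 0.643, 0.643, 0.643 and 0.784 with the estimated correlation. Inner retina was lost without WT replicate 1 (0.0684), 3 (0.0501), 4 (0.0676) or 5 (0.0582) or CRISPANT replicate 1 (0.103), 2 (0.0586) or 4 (0.0695), and lens without WT replicate 1 (0.108) or CRISPANT replicate 1 (0.103) or 5 (0.0625). Without WT replicate 6 the counts became 1 raised and 20 lowered for central neurons, 0 and 6 for the inner retina and 2 and 14 for the cell cycle (edgeR).

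Of 45 cranial neural crest genes 7 rose and 3 fell (7 and 3 adjusted over the list alone), with snai2 (log2 0.32, edgeR adjusted p = 0.000519), snai1b (0.40), pax9 (0.34) and msx2b (0.38) raised. Of 33 periocular and anterior segment genes 5 rose and 1 fell (9 and 2 adjusted over the list alone), with the laminin gene lamb2 (0.26) and the keratan sulfate proteoglycan gene lum (0.31) up and lmx1bb (-0.22) down, and 8 rose and 2 fell without WT replicate 6. Of 36 optic fissure genes 7 rose and 2 fell (7 and 5 adjusted over the list alone), with znf703 (0.20) and tfeb (0.27) up. Of 12 paired homeobox genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), with prrx1b up (0.26) and shox (-0.25) and uncx (-0.26) down. In the cartilage list 2 of 41 genes rose and 0 passed adjusted over the list alone (edgeR), and in bone 5 of 29 rose and 1, the proton pump gene tcirg1a (-0.39), fell (5 and 1 adjusted over the list alone). Camera adjusted p was 0.57, 0.274, 0.537, 0.0831, 0.285 and 0.0575 for these 6 lists. Without WT replicate 6, 1 cartilage gene rose, and 4 bone genes rose and 2 fell. Paired homeobox passed without WT replicate 1 (0.0473) or 2 (0.0378), and bone without WT replicate 1 (0.0423), 2 (0.0485) or 4 (0.0282) or CRISPANT replicate 3 (0.0179). With all samples both lists had a camera adjusted p of 0.643 with the estimated correlation, which was not run for these fits.

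Of 23 erythroid genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), with the erythropoietin receptor gene epor (log2 -0.58, edgeR adjusted p = 0.00507) and epb41b (-0.66) down. Of 63 muscle genes 7 rose (1 adjusted over the list alone), including the parvalbumin gene pvalb3 (0.52), and of 17 heart genes gata6 (0.47) alone rose (1 adjusted over the list alone). Of 55 vasculature genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with dusp5 (0.68) up and gata2a (-0.25) and dll4 (-0.23) down. Both vasculature counts lie below the shares over all genes. Of 47 skin genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with the ionocyte gene slc12a10.2 (1.00) up and pkp1b (-0.65) down, and 6 rose and 5 fell without WT replicate 6. Of 58 photoreceptor genes 1 rose, guca1aa (0.81), and 1 fell, rgs9b (-0.31), with 1 and 1 adjusted over the list alone, and the list had a median fold of 0.997, a mean log2 of 0.02 and an upward test. Camera adjusted p was 0.025, 0.0593, 0.57, 0.56, 0.274 and 0.77 for these 6 lists. Erythroid (0.643 with the estimated correlation) was lost without WT replicate 6 (0.192) or CRISPANT replicate 4 (0.0569) or 5 (0.0625). Muscle passed without WT replicate 1 (0.0273) or 6 (0.0178) or CRISPANT replicate 3 (0.00688), 4 (0.047) or 5 (0.0104), but without WT replicate 6 it had a camera adjusted p of 0.765 with the estimated correlation. Skin passed without CRISPANT replicate 6 (0.042). With all samples skin had a camera adjusted p of 0.827 with the estimated correlation, which was not run for that fit. Photoreceptors turned downward without WT replicate 6 (camera adjusted p = 0.0295, and 0.766 with the estimated correlation), with 1 gene raised and 2 lowered, and in heart 1 gene rose and 1 fell without that sample.

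Of the 29 lists tested in CRISPANT against WT, 16 passed camera with the preset correlation, 11 of them up, and none with the estimated correlation (smallest camera adjusted p = 0.312). With fry 9 of the 16 passed, among them retinoic acid (adjusted p = 0.00165), myelin and glia (0.0023), melanophore (0.00261), clock (0.00384) and stress (0.00512).

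**Figure D3:**
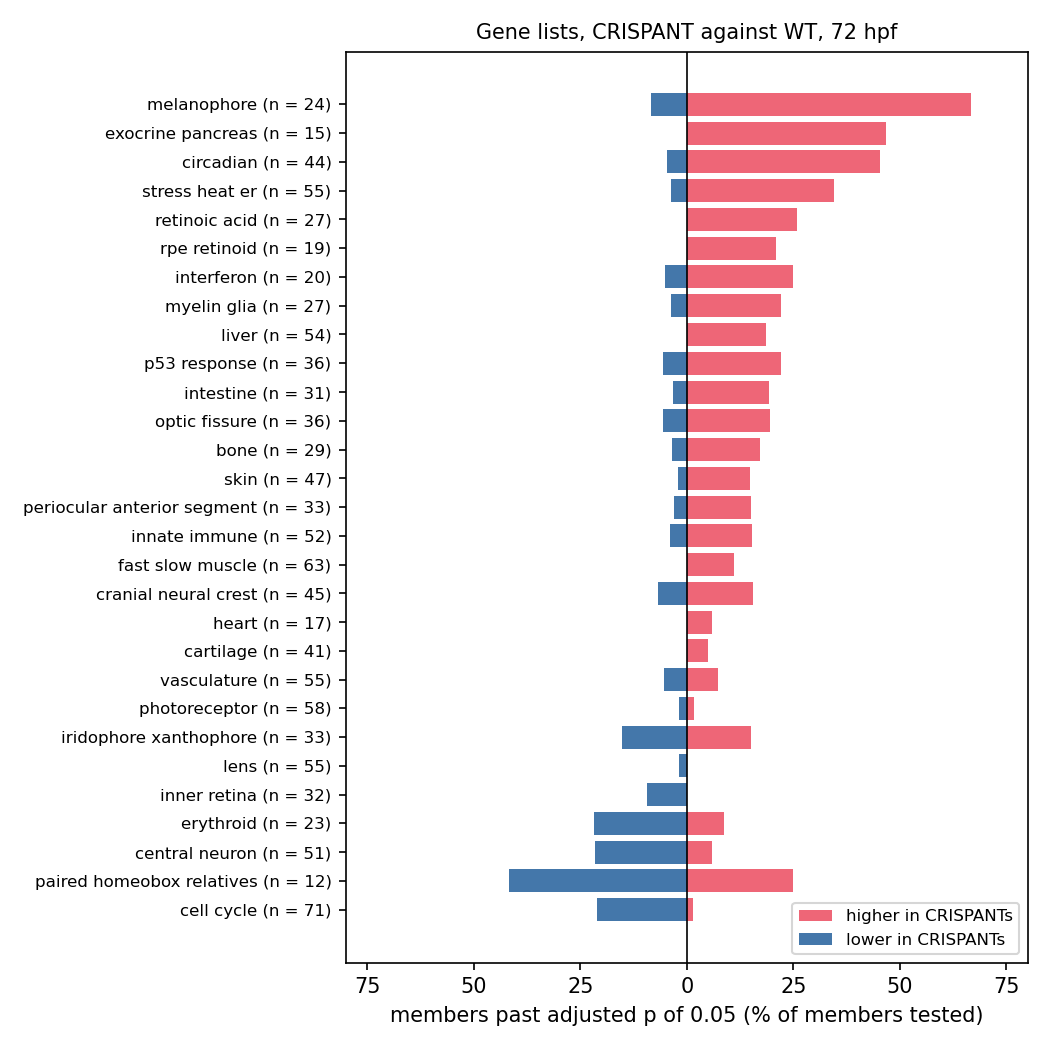
Percentage of tested genes in each of 29 lists that passed an edgeR adjusted p of 0.05 in CRISPANT against WT (n = 6 each), with raised genes to the right and lowered genes to the left. Melanophore genes had 16 raised and 2 lowered of 24, and cell cycle genes 1 raised and 15 lowered of 71.

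Whether called genes gathered near the mutated genes was also asked at 72 hpf, again with genes taken as independent. On chromosome 8, 159 of 916 genes were called (17.4% against 18.7% elsewhere, odds ratio 0.914, Fisher's exact p = 0.319). On chromosome 18, which carries alx1, 148 of 683 were called (21.7% against 18.5%, odds ratio 1.22, Fisher's exact p = 0.0406). Among genes changed at least 2-fold, chromosome 18 held 14 of 683 (2.05% against 0.937% elsewhere, odds ratio 2.21, 95% interval 1.18 to 3.83, Fisher's exact p = 0.0083), but within 10 Mb of alx1 the odds ratio was 1.05 (0.213 to 3.13). That last interval includes 2.21, so it does not show that the excess is absent near alx1. Over all called genes the odds ratio within 10 Mb of alx1 was 1.35 (95% interval 1.02 to 1.77, Fisher's exact p = 0.0316). It was 1.13 (Fisher's exact p = 0.328) there at an adjusted p under 0.1. Within 5 Mb it was 1.14 (Fisher's exact p = 0.447) at an adjusted p under 0.05. C7H19orf12, uraha, cyba, mapk6, serf2a and cd82b all lie on chromosome 18.

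Genes called in CRISPANTs were then followed in alx1;alx3 against alx1. The 2024 raised genes that were tested there had a median log2 of -0.148, with 29.8% higher, and the 1669 lowered genes had a median of 0.116, with 67.1% higher, against -0.019 and 47.6% for all genes. Both shifts ran opposite to the CRISPANT direction (camera p = 6.62e-07 and 1.19e-06, and 0.0148 and 0.0324 with the estimated correlation). They were not tested with single embryos left out, although the germline call count changed with them. Both germline groups are alx1 mutants, while CRISPANT against WT also holds the loss of alx1 and another age. Of the 4 genes called in alx1;alx3 embryos, all lower there, si:ch73-281k2.5 was lower in CRISPANTs too (log2 -0.39, edgeR adjusted p = 0.00959). Chance gives 0.35 genes lowered in both. p2rx7 (-0.11, edgeR adjusted p = 0.626), elovl8b (0.18, 0.3) and si:ch73-237c6.1 (-0.1, 0.228) did not pass in CRISPANTs.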

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

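The tests of the heterozygote position, of the chromosome 8 odds, of the label and depth of alx1 replicate 1, of the clock arms, and of the splits without alx1 replicate 1 were chosen after the results were seen. The stage score and the other splits were planned.

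Of 314 values tested within groups of 4 or 6 samples, 18 (5.73%) had 1 sample far from the rest, and chance does this in about 1 in 20 groups. The number given is the gap to the nearest sample over the group's whole range. In the germline set these were elovl8b in alx1 replicate 3 (0.865, at 5.73 against 3.15 CPM), hvcn1 in alx1;alx3 replicate 2 (0.896), and the total count of alx1;alx3/+ replicate 4 (0.897). In the 72 hpf set the total count of WT replicate 3 stood apart (0.858), as did snai1b in WT replicate 4 (0.676), eif2ak2 in WT replicate 3 (0.706) and ca2 in WT replicate 1 (0.717). WT replicate 6 stood apart for nr1d2b (0.637), acta1b (0.714), cyp3a65 (0.732), stra6 (0.65) and cyp26c1 (0.713). Among CRISPANTs it was replicate 2 for fndc7rs4 (0.643) and stra6 (0.75), and replicate 4 for nfil3-6 (0.666), crygm2e (0.821), c3a.3 (0.634) and cyp26c1 (0.645).

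The first pattern is that the genes edgeR called in the germline carriers of alx3 with all embryos lie on chromosome 8, although DESeq2 called 136 of 165 genes elsewhere for alx1;alx3 and 5 of 19 for alx1;alx3/+, and edgeR with only the 2 genotypes compared called 2 of 6 elsewhere for alx1;alx3/+. Alleles linked to alx3 that act additively would put the heterozygotes midway, but over 8 genes spanning 18.2 to 41.2 Mb their median position between alx1 (0) and alx1;alx3 (1) was 0.968 (quartiles 0.874 to 0.998), with zgc:152830 at 0.591. Parents that differ genome-wide would spread the genes that part alx1 from the 8 other embryos over all chromosomes, but 11 of 16 lay on chromosome 8 (odds ratio 49.4, 95% interval 15.8 to 182). These genes come from the same embryos as the calls on chromosome 8, so this count is not independent of them. Linked alleles that act dominantly, parents that differ mainly on chromosome 8, and an effect of alx3 itself may each be the source, and none of them was tested. The sample titles call the germline embryos siblings. Of the 35 splits of these samples, the real one included, 3 gave as many genes for alx1;alx3 (real 4, highest other 1654) and 4 for alx1;alx3/+ (real 3, highest other 2116), so chance cannot be excluded for either count.

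The second pattern is that alx1 replicate 1 stands apart, with a mean squared deviation of 0.311 against 0.121 to 0.179 in the other germline embryos. The splits with 1654 and 2116 genes both place it with alx3 carriers. Each also places a carrier with the remaining alx1 embryos, alx1;alx3 replicate 4 for 1654 and alx1;alx3/+ replicate 1 for 2116. These splits cannot tell a swapped label from another structure of the samples. A first label test used 27 chromosome 8 genes of at least 2-fold in alx1;alx3 against alx1, chosen without alx1 replicate 1 and alx1;alx3 replicate 4. It gave alx1 replicate 1 a median position of 0.708 (quartiles 0.188 to 0.902) between the other alx1 embryos (0) and alx1;alx3 replicates 1 to 3 (1). This went toward a wrong label, with alx1;alx3 replicate 4 at 0.667 (0.488 to 0.897). A different test, chosen after that result was seen, used 8 genes of at least 4-fold in alx1;alx3/+ against alx1 with the alx1;alx3/+ embryos at 1, and gave -0.0696 (-0.12 to 0.00308), with alx1;alx3 replicate 4 at 0.944 (0.864 to 1.01), which argues against an alx3 carrier, though less firmly than if the first test had gone the same way. Low depth is argued against by a deviation 1.75 times the highest among 3 libraries of the same or lower total count. The stage, parents or health of this embryo stay open and were not tested.

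The third pattern is the broad set of list differences between CRISPANT and WT, with 4024 genes called. Among the other 99 splits drawn from 462 the highest count was 739, in the split that exchanges only WT replicate 6 and CRISPANT replicate 6. That split keeps most of the real grouping. None of the 99 gave as many genes as the real split (1 of 100, the real one included). This argues against a chance split of these samples for the gene count. The lists were not put through the splits. Nor can the splits exclude a chance difference between clutches or pools, because the labels do not say how the samples were drawn. A later stage of the CRISPANTs may contribute, since a score from genes that differ between 72 hpf and 5 dpf was higher in CRISPANTs than in held-out WT by 0.239 (exact p = 0.0357) and 0.545 (exact p = 0.0119, the smallest possible), although kit and genotype also differ between the sets. The held-out WT samples behind 0.545 include WT replicate 6 and had an SD of 0.403, against 0.147 behind 0.239. The 5 dpf end of the score came from alx1;alx3/+ embryos, which like the CRISPANTs are alx1 mutants. The score therefore cannot separate a later stage from the loss of alx1. Another time of day at harvest cannot be told apart from an effect of genotype, because the activator arm of the clock had a median log2 of -0.01 (95% interval -0.04 to 0.16) while the output arm had 0.36 (0.23 to 0.67), and no harvest time was analysed here. Genotype, parents and injection differ together between the groups and stay open.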

How the results depend on the processing

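Leaving out the chromosomes of the mutated genes, DESeq2, limma-voom and the filters were planned. The list counts without alx1 replicate 1 and without WT replicate 6 were chosen after the data were seen.

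In alx1;alx3 against alx1 (4 genes), the count was 165 with DESeq2, 2 with the file letter as a block, 2 with only the 2 genotypes compared, 2 with effective-length offsets, 0 without the chromosomes of the mutated genes, and 1 to 1105 in leave-one-out fits, highest without alx1 replicate 1. In alx1;alx3/+ against alx1 (3 genes), it was 19 with DESeq2, 1 with the file letter, 6 with only the 2 genotypes compared, 0 without those chromosomes, and 1 to 2 in leave-one-out fits. In alx1;alx3 against alx1;alx3/+ (0 genes), it was 9 with DESeq2 and 0 to 1 in leave-one-out fits. The count of 0 without those chromosomes follows from the called genes lying there, and otherwise the cause was not tested. CRISPANT against WT (4024 genes) stayed within 2839 to 4639 in leave-one-out fits and at 3694 with no filter.

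In the germline set replicate numbers did not pair the samples (2 of 12 same-number pairs had r above 0.1, range -0.4 to 0.29). At 72 hpf 1 of 6 same-number pairs had r above 0.1, but all 6 were above 0 (0.01 to 0.26). Pairing by number was therefore not excluded there, and the main fit leaves it out. With replicate numbers as a block the counts were 1, 1, 0 and 4729 in the order above. The block ended the calls of p2rx7 and elovl8b in alx1;alx3 (edgeR adjusted p = 0.168 for both) and in alx1;alx3/+ (0.394 and 0.155). The fold changes stayed large, with log2 of -5.92 for p2rx7 and -2.64 for elovl8b in alx1;alx3 and -3.18 for elovl8b in alx1;alx3/+.

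The chromosome 18 odds ratio was 1.17 (Fisher's exact p = 0.0713) at an adjusted p under 0.1. Photoreceptors reversed without alx1 replicate 4 in alx1;alx3 (camera adjusted p = 0.317, leave-one-out range 0.000169 to 0.317) and in alx1;alx3/+ (0.213, range 3.35e-06 to 0.213), and without WT replicate 6 in CRISPANTs (0.0295, range 0.0295 to 0.921). Muscle reversed in alx1;alx3/+ without alx1 replicate 4 (0.017) or alx1;alx3/+ replicate 2 (0.018), with a range of 0.000873 to 0.744. Lens reversed in alx1;alx3 against alx1;alx3/+ without alx1;alx3/+ replicate 2 (1.2e-08, range 1.2e-08 to 0.815). With all embryos lens had a camera adjusted p of 0.932 there with the estimated correlation, which was not run for that fit. The causes were not tested.

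For named genes of CRISPANT against WT, 120 of 120 kept direction and call with DESeq2 and with limma-voom, and 1374 of 1440 in leave-one-out fits. For its lists 316 of 348 did in leave-one-out fits, while all 16 calls were lost with the estimated correlation. On simulated data 49.3%, 38.8% and 35.8% of 2-fold changes were recovered in the 3 germline comparisons and 95.5% at 72 hpf, so smaller germline changes were mostly not detectable.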

Other observations

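The list counts without alx1 replicate 1 and without WT replicate 6 were chosen after the data were seen, as was the weighing of chromosome 18.

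In alx1;alx3 against the 3 other alx1 embryos, without alx1 replicate 1, 15 of 42 cartilage genes rose (26 adjusted over the list alone), of 53 central neuron genes 12 (22 adjusted over the list alone, and so for each count in parentheses that follows), of 36 optic fissure genes 6 (13), of 34 periocular genes 7 (8, with 1 lower) and of 46 cranial neural crest genes 5 (10). The neural crest factor gene sox10 had a log2 fold change of 2.07 (edgeR adjusted p = 0.0307), the chondrocyte factor gene sox9a 0.97 (0.0312), the periocular mesenchyme factor gene foxc1a 1.37 (0.0307) and the optic fissure gene vax1 1.21 (0.0347). With all embryos sox10 was at 1.3 (0.27), sox9a at 0.68 (0.262), foxc1a at 0.78 (0.34) and vax1 at 0.86 (0.275). The genes named in this paragraph were chosen after their values were seen. Without alx1 replicate 1, 862 of all 21162 genes rose and 243 fell, and the list counts are to be read against these. Of 58 liver genes 11 fell (22), of 43 intestine genes 6 (14) and of the exocrine pancreas genes 3 (8), with the fibrinogen gene fgb at -0.92 (0.0312) and the transferrin gene tfa at -1.03 (0.0312). With all embryos fgb was at -0.75 (0.253) and tfa at -0.87 (0.253). Without alx1 replicate 1 no list passed with the estimated correlation (camera adjusted p = 0.235 for cartilage and 0.209 for the optic fissure). In splits of these 7 embryos the real one gave 1105 genes and the highest other 23 (1 of 35 as large, the real one included), but these 7 embryos were taken after the count of 1105 was seen, so the splits do not exclude chance.

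In alx1;alx3/+ against alx1 without alx1 replicate 1 no list member passed over all genes (edgeR), and adjusted over the list alone 20 cartilage, 7 bone, 7 periocular, 4 optic fissure and 4 neural crest genes were higher. For alx1;alx3 against alx1;alx3/+, all 35 of 35 splits gave as many genes as the real one (real 0, highest other 1).

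That chromosome 18 carries more genes changed by 2-fold or more in CRISPANTs (odds ratio 2.21) was first weighed as linkage to alx1 and then left out of the patterns weighed. Within 10 Mb of alx1 the odds ratio was 1.05, from 3 of 306 genes (interval 0.213 to 3.13). That interval includes 2.21, so the window cannot tell whether the excess is present near alx1. Over all called genes the odds ratio there was 1.35 (Fisher's exact p = 0.0316), but 1.13 (0.328) at an adjusted p under 0.1. Within 5 Mb it was 1.14 (0.447) over all called genes. Chromosome 4 had 41 genes changed by 2-fold or more (3.43%), which does not bear on linkage to alx1. Linkage to alx1 stays open.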
